A study of Mus musculus with 14 samples.

How the data were processed

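RNA from 14 frozen samples of liver and liver tumour of 8 MF-1 outbred mice was measured by the authors on Affymetrix expression arrays, from 6 µg of Trizol-extracted total RNA per array labelled with biotin. Per the submitters' processing notes, the deposited values are log2 values made with GCRMA, a method that corrects background by probe GC content, normalizes the arrays and summarises probes to probe sets, in Affymetrix Expression Console. The versions of both, and whether the 2 runs were normalized together, are not given in the sources used here. The deposited table held 22690 probe sets and 14 columns with values from 1.24 to 15.79. Raw array files and detection calls were not used here, and the values were taken as deposited, without a further normalization. Array medians ran from 4.54 to 5.03. An array has no read depth, so the number of arrays and of mice limits the precision.

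The platform annotation gave a gene for 21084 probe sets. The 691 probe sets with several genes and the 1606 without a gene, which include 64 control probe sets, were left out, so 20393 probe sets for 12394 genes remained. For the 4958 genes with more than 1 probe set, the probe set with the highest mean over the 14 arrays was used. A gene was tested if that probe set lay above the median of the array in at least 2 arrays, which left 7641 genes. H19, Ddx3y, E2f2, E2f7 and Tfdp2 had no probe set that matched a single gene, and E2f3, E2f4, Igf2 and Gpc3 lay below the filter.

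Groups came from the sample labels: 6 tumours, 3 livers around tumours, 3 livers of transduced mice without tumours and 2 livers of untransduced mice. The labelled sex and the array run are the same split, with 9 arrays in the female run and 5 in the male run. Tumours were compared with surrounding liver in a fit of those 9 arrays with mouse as a block. The 8 non-tumour livers, 1 per mouse, shared a fit with group and run as terms, which gave the 3 comparisons between liver groups and the comparison of the runs. For tumours against livers of other mice, the 2 tumours of a mouse were averaged, so that the mouse was the replicate, and the fit of 8 mice had group and run as terms. A further fit tested whether the tumour difference varied between mice. Differences within 1 run came from a fit of all 14 arrays with a mean for each group in each run. That fit takes its spread from all 14 arrays, so a lone liver is assumed to vary like the other groups. Each fit used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 7641 genes of that comparison. SE stands for the moderated standard error of a fitted log2 difference, and SD for the spread between samples.

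Lists of genes by pathway or cell type were written from textbook knowledge, 42 in all, and the 32 with at least 10 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera compares the genes of a list with all other genes; its alternatives were camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance. A list's median is the median log2 difference of its tested members. Its percentile in a tumour is that median's rank among 10000 random lists of the same size, drawn from genes of like mean level. The percentile takes no account of correlation between the members. Some genes sit in several lists. For each list described, the number of members past the threshold over all genes is given beside the number when adjusted over the list alone.

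The rule for named genes was as follows. For tumours against surrounding liver, the 10 largest rises and 10 largest falls past the threshold with the same sign in all 6 tumours were to be named. For other comparisons the rule took the 5 largest each way past the threshold, all if fewer, or the 3 with the smallest p if none passed. For each list described it took up to 4 passing members by p, or the 2 largest differences if none passed. E2F and RB family genes, Afp, H19, Igf2, Gpc3, Glul, Alb, Mki67, Xist and Y-linked genes were named whatever their values, and predicted genes, clone names and probe sets with several genes were skipped. The groups, comparisons, lists, this rule and all alternatives except 5 were fixed before the data were examined. The alternatives were: no filter or a stricter filter; quantile normalization again; the mean of a gene's probe sets, or all probe sets; no intensity trend; a 2-fold minimum; the female run only; contrasts within each run; all 14 arrays with mouse as a random block (statmod 1.5.0); no mouse block; averaged tumours; no run term; only the groups compared; and each replicate left out in turn. The 5 added after seeing the data tested the lists without the tumour labelled F1-T2 (for genes this is 1 of the planned leave-outs), did so with an estimated correlation, left out 6 libraries labelled female with Y-linked signal, took the Eif2s3y level as a covariate, or left out the 2 non-tumour livers with Xist signal.

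The fits were tested on simulated data in which 200 of 7641 independent genes differed, shared about equally among log2 sizes of 1, 2 and 4. In 20 such sets, limma called 64.2% of the genes that differed by 2 for tumours against surrounding liver and 80.6% for surrounding against tumour-free liver. Unchanged genes made up 5.36% and 5.08% of the calls over all 3 sizes. Real genes are correlated, which the simulation leaves out. Figures were drawn with matplotlib 3.10.9.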

Results

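Expression was profiled in liver and liver tumours of mice whose livers had been transduced before birth. Lentiviral vectors derived from feline immunodeficiency virus (FIV) had been given into the yolk sac vein of fetuses at gestation day 16, and hepatocellular carcinomas appeared in some of the animals. The 14 arrays covered 6 tumours, 2 from each of the mice M1, F1 and F2, and the liver around the tumours in those 3 mice. Liver of the tumour-free transduced mice M2, F3 and F4 (n = 3) and of the untransduced mice M-control and F-control (n = 2) completed the set. Ages ranged from 273 days (F2) to 715 days (F3) in the transduced mice, and those of the 2 controls are not given in the sources used here. Albumin (Alb), the main secreted protein of hepatocytes, lay between 15.48 and 15.70 on the log2 scale in all 14 libraries.

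Sex-linked transcripts did not follow the labelled sex in every library. Xist, the RNA that silences an X chromosome in female cells, was 10.46 in the surrounding liver of F1, 12.78 in its tumour F1-T1 and 9.69 in the tumour-free liver of F3. In the other 6 libraries labelled female it was at most 2.05, and the Y-linked gene Eif2s3y lay between 8.91 and 9.78. Those 6 libraries were the liver and both tumours of F2, the livers of F4 and F-control, and the library labelled F1-T2. All 5 libraries labelled male carried Y-linked signal, and their highest Xist value was 2.20 on the same probe set. A second Xist probe set was 6.47 in the tumour M1-T1, 9.66 to 11.14 in the 3 libraries with Xist signal, and at most 2.60 in the other 10. The runs also differed in a sign of RNA quality. The 3' minus 5' signal of beta-actin was 1.26 ± 0.223 (SD, n = 9) in the female run and 3.15 ± 0.316 (n = 5) in the male run, and that of Gapdh was 0.308 ± 0.224 and 1.66 ± 0.811.

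**Figure D1:**
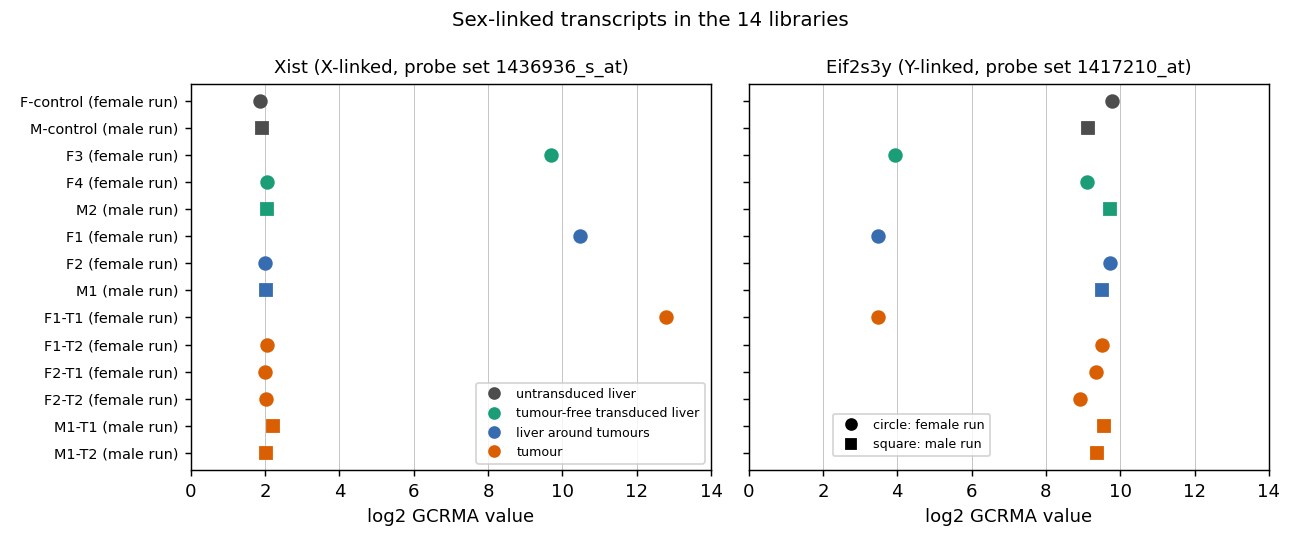
Log2 GCRMA value (x axes) of Xist and of the Y-linked gene Eif2s3y in each of the 14 libraries (y axis), with colour for the group and shape for the run. Of the 9 libraries of the female run, 3 carried Xist signal between 9.69 and 12.78, and 6 carried Eif2s3y signal between 8.91 and 9.78.

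Tumours against the liver around them in the same mouse show what set tumour tissue apart from its host liver. Transcripts of dividing cells were high in 5 of the 6 tumours. All 32 measured mitosis and G2/M genes had a higher fitted value in tumour, with a median difference of 2.55 on the log2 scale. Ccnb2, which encodes cyclin B2, was 6.96 ± 2.69 (SD, n = 6) in tumours and 2.33 ± 0.118 (n = 3) in surrounding liver, a fitted difference of 4.64 (SE 1.36). Its mean in surrounding liver lies below the lower quartile of those arrays (2.42 to 2.45), near background, so the size of this difference is not exact. The differences were 4.30 (SE 1.56) for Top2a, a topoisomerase of replicating cells, and 4.19 (SE 1.44) for the proliferation marker Mki67, and each of these 3 genes was higher in 5 of 6 tumours. Of 37 targets of E2F transcription factors and DNA replication genes, 36 were higher, with a median of 2.00, among them the helicase gene Hells at 3.76 and the replication licensing gene Mcm6 at 3.64. Both lists passed camera, with adjusted p = 1.8e-17 and 7.6e-15. No member of either passed over all genes or when adjusted over the list alone, and with an estimated correlation each list had adjusted p = 0.455.

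In limma 0 of 7641 genes passed in this comparison, where 667 had an unadjusted p under 0.05 (352 higher and 315 lower in tumour) and chance gives 382. The lowest adjusted p was 0.530, so none of the genes named here as higher or lower in tumours passed. The count was 0 as well without the replicate block (535 unadjusted) and with the 2 tumours of a mouse averaged inside the block (743). It was also 0 within the female run (888) and within the male run (72), with the spread of all 14 arrays, and the second says little because it rests on 1 mouse. The fit within the runs has no mouse term, so the 2 tumours of a mouse count as separate samples there and are not paired with their own liver. In the fit with mouse as a block, the count depended on the library labelled F1-T2: when each array was left out in turn, 12 genes passed without it, all higher in tumour. They included Ccnb2 at 5.66, Top2a at 5.51, Mki67 at 5.33, Cdc20 at 5.24 and the fatty acid binding protein gene Fabp4 at 3.07. With mouse as a block, the 2 tumours of a mouse count as separate samples too, though they share 1 surrounding liver. The p and SE of that fit may therefore come out too small, and averaged tumours were not fitted without F1-T2. Without the 6 libraries labelled female with Y-linked signal, 0 genes (255 at an unadjusted p under 0.05) and 17 lists passed.

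The E2F and RB family had 8 tested genes, too few for a set test. Rbl1, which encodes the RB relative p107, differed by 2.73 (SE 1.25) and was higher in 5 of 6 tumours. E2f1 lay at 6.69 in F1-T1, 5.59 in F2-T2 and 4.82 in F2-T1, and between 3.32 and 3.75 in all other libraries, a fitted difference of 1.18 (SE 0.718). The fitted differences of Tfdp1, E2f8 and Rb1 were 0.87, 1.12 and 0.49. Within the male run E2f8 and Rb1 were at -0.015 and -0.33, and E2f5 (0.14), E2f6 (-0.04) and Rbl2 (-0.04) changed sign under some alternatives as well. None of these 8 genes passed, and E2f3 and E2f4 stayed at or below 3.37 in every library.

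Genes of hepatocyte metabolism had lower fitted values in tumours as sets, though not in every tumour. All 18 cholesterol synthesis genes had lower fitted values, with a median of -1.49, the mevalonate pathway gene Mvd at -2.47 and Tm7sf2 at -1.98. Of 38 cytochrome P450 and drug metabolism genes, 34 were lower, with a median of -0.80, including Cyp2c37 at -3.67 (lower in 6 of 6 tumours). Those 6 include the library labelled F1-T2, whose sex-linked transcripts did not match the liver of F1 that it is compared with. The median was -0.75 for 22 bile acid genes, of which 20 were lower, including the synthesis enzyme Cyp8b1 at -3.24 and the uptake carrier Slco1b2 at -3.01. Of 23 genes of fatty acid synthesis and storage, 19 were lower, with a median of -0.82 and the acetyl-CoA carboxylase gene Acacb at -2.97 (SE 0.724). Camera's adjusted p for these 4 lists was 1.7e-08, 4.0e-08, 3.6e-05 and 8.6e-06 in this order, and 0.455 for each with an estimated correlation. Over all genes 0 of their members passed. Adjusted over the list alone, 9 of the fatty acid genes passed, 1 of them higher, and 0 of the other lists. All 4 lists had negative medians in M1-T1, F1-T1 and both F2 tumours. In M1-T2 and F1-T2 the medians were 0.04 and 0.22 for cholesterol and -0.035 and 0.20 for bile acid genes. They were -0.135 and -0.02 for P450 genes, and 0.06 and -0.78 for fatty acid genes.

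Markers of liver zones were lower too. The 18 pericentral genes and beta-catenin targets had a median of -1.89, with 17 lower, among them Cyp1a2 at -3.71. Glutamine synthetase (Glul), a pericentral enzyme, differed by -1.31, and within the male run Cyp1a2 and Glul were at 0.035 and 0.545. The 13 periportal genes had a median of -0.58, with 10 lower, Hsd17b6 at -3.99 and the histidine ammonia-lyase gene Hal at -1.88. Camera gave adjusted p = 1.1e-05 and 0.017 for these lists, and 0.590 and 0.604 with an estimated correlation. The pericentral call was lost without mouse F2 (adjusted p = 0.0642) and the periportal call without M1 (0.192). Neither list had a member past the threshold over all genes or adjusted over the list alone.

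Among cell type markers, 17 of 19 genes of macrophages and Kupffer cells had lower fitted values, with a median of -0.66, Marco at -3.66 and Cd163 at -3.58. The tumours differed here. The list median was -2.38 in M1-T1, -1.02 in F1-T1 and -1.61 in the library labelled F1-T2. It was 0.72 in M1-T2, 0.06 in F2-T1 and -0.09 in F2-T2, so the fall was not shared by all tumours. Stellate cell and fibroblast markers were lower in 7 of 10, with a median of -1.25. Pdgfra was at -2.66 and Dcn at -2.61, each lower in 6 of 6 tumours, the mismatched library labelled F1-T2 among them. Camera's adjusted p was 0.0015 and 0.0022, and 0.604 and 0.455 with an estimated correlation, and the macrophage call was lost without mouse F1 (0.199). Over all genes 0 of these markers passed, and 2 stellate markers did when adjusted over the list alone.

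Other lists rose or fell as sets. All 26 ribosomal protein genes had higher fitted values, with a median of 0.34 and Rplp0 at 0.58. Of 17 tumour and fetal liver markers 14 were higher, with a median of 1.25. Vil1 was at 5.08 and Afp at 3.79, each higher in 6 of 6 tumours, the mismatched library labelled F1-T2 among them. Male-biased liver genes had a median of -1.36, with Elovl3 at -4.12 and Mup3 at -3.21. Camera's adjusted p for these 3 lists was 1.6e-07, 0.012 and 0.0068, and 0.455, 0.455 and 0.623 with an estimated correlation. The tumour marker call was lost without M1 (0.0974), and the male-biased median turned to 0.26 without F2. No member of the 3 lists passed over all genes or when adjusted over the list alone.

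The remaining 5 of the 18 lists past camera had adjusted p from 0.0011 to 0.039, and 0.455 or 0.604 with an estimated correlation. They were PPAR-alpha and fatty acid oxidation genes (median -0.44, Vnn1 3.06, Acaa1b -1.80), NRF2 targets (-0.44, Abcc3 -2.85, Gsta2 -1.91), immediate early genes (0.62, Jun 1.78, Atf3 1.70), secreted hepatocyte proteins (-0.10, C8a -2.80, C8b -1.93) and the proteasome (0.12). Each call was lost without 1 mouse: F1 for PPAR-alpha genes (adjusted p = 0.213) and the proteasome (0.199), F2 for NRF2 targets (0.0648) and immediate early genes (0.455), and M1 for secreted proteins (0.116). No member passed over all genes or when adjusted over the list alone. The 27 type I interferon response genes did not pass (median 0.55, adjusted p = 0.11, Oas2 2.84, Cxcl10 2.28), but passed without the library labelled F1-T2 (median 0.98, adjusted p = 1.2e-05, and 0.468 with an estimated correlation), both list tests chosen after seeing the data.

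**Figure D2:**
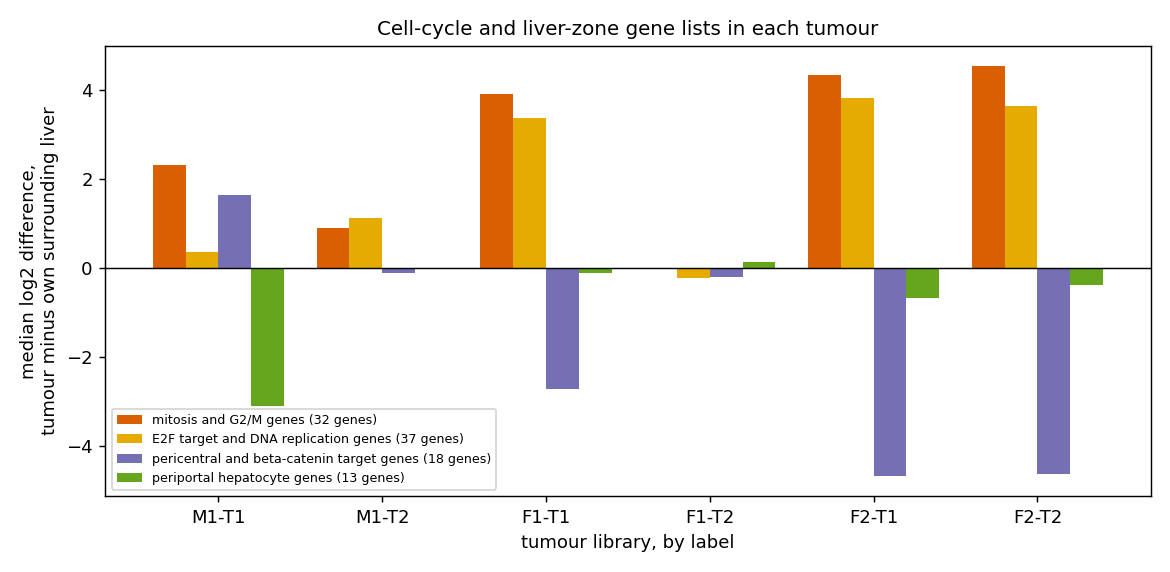
Median log2 difference between each tumour and its own surrounding liver (y axis) for 4 gene lists, by tumour library (x axis). Mitosis genes stand at 0.90 or above in 5 tumours and at 0.005 in F1-T2, and pericentral genes stand at 1.65 in M1-T1 and at -2.71 or below in F1-T1 and both F2 tumours.

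The tumours were unlike each other. The mitosis list had a median of 4.34 in F2-T1, 4.54 in F2-T2, 3.92 in F1-T1, 2.33 in M1-T1 and 0.90 in M1-T2, each at percentile 100 of random lists, and of 0.005 in F1-T2. Pericentral genes were at 1.65 in M1-T1 and at -4.67 in F2-T1, -4.63 in F2-T2 and -2.71 in F1-T1, while periportal genes were at -3.10 in M1-T1 and between -0.66 and 0.15 in the other 5 tumours. Interferon genes were at 1.82, 1.5, 0.81 and 0.76 in F2-T2, F2-T1, F1-T1 and M1-T2, and at -0.27 in M1-T1 and -1.91 in F1-T2. Differences against own surrounding liver correlated across genes, which are not independent replicates, with r = 0.653 and 0.688 between F1-T1 and the 2 tumours of F2. The 2 tumours of a mouse share the liver they are compared with, which by itself raises their r, so values within a mouse cannot be set beside those across mice. Within a mouse r was 0.933 for F2 and 0.175 for M1. It was 0.133 between the 2 libraries labelled as tumours of F1. These differ in Xist and Y-linked signal, so this r cannot be taken as a value within 1 mouse. A difference of at least 2-fold was seen in 2406 genes in F2-T1 and in 580 in M1-T2. The limma test of a tumour difference that varies between the 3 mice called 0 of 7641 genes (204 at an unadjusted p under 0.05, lowest adjusted p 0.978), and the contrast of M1 with the mean of F1 and F2 called 0 (143 unadjusted, 0.998). Both took their spread from the 2 tumours of each mouse, with 3 residual degrees of freedom. For F1 these include the library labelled F1-T2, which differed from F1-T1 in sex-linked transcripts, so 0 calls say little.

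Liver around tumours against liver of transduced mice without tumours asks how the livers of tumour-bearing mice differed. Interferon response genes stood out. Irf7, the transcription factor that drives type I interferon production, was 8.86 ± 1.2 (SD, n = 3) in surrounding liver and 5.68 ± 0.818 (n = 3) in tumour-free liver. It rose by 3.18 (SE 0.24) and was the only gene past the threshold in limma (adjusted p = 0.0342), among 693 at an unadjusted p under 0.05 (493 higher and 200 lower). Each surrounding liver (7.43 in M1, 9.54 in F1, 9.62 in F2) lay above each tumour-free liver (4.75 to 6.29). The gene is on chromosome 7 and has Entrez identifier 54123. Of 27 type I interferon response genes, 26 were higher in surrounding liver, with a median of 1.15 and a camera adjusted p = 1.3e-17. Of these, 1 passed over all genes and 19 when adjusted over the list alone, and with an estimated correlation the list had adjusted p = 0.680.

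Kupffer cell and vessel markers moved with them. Macrophage and Kupffer cell markers were higher in 17 of 19 cases, with a median of 0.60, the scavenger receptor Marco at 2.13 and the Fc receptor Fcgr1 at 1.48. Liver endothelial markers were higher in 16 of 18, with a median of 0.36, Lyve1 at 1.12 and Tie1 at 1.18. Acute phase genes were lower in 18 of 23 cases, with a median of -0.74, the metallothionein Mt2 at -2.75 and the serum amyloid gene Saa2 at -2.64 (0.51 within the male run). ER and amino acid stress genes were lower in 18 of 22, with a median of -0.21, Asns at -1.77 and Psat1 at -1.45, and ribosomal protein genes were higher in 22 of 26, with a median of 0.18 and Rps25 at 1.15. Camera's adjusted p was 0.0027, 0.00057, 2.6e-07, 0.00044 and 0.033 in this order, and 0.927, 0.805, 0.927, 0.805 and 0.927 with an estimated correlation. No member passed over all genes, and 1 macrophage, 2 endothelial and 1 acute phase gene passed when adjusted over the list alone. The macrophage call was lost without F4 (0.412), and the endothelial (0.182) and ribosomal (0.902) calls without F1.

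The call for Irf7 was lost when any 1 of the 6 livers was left out, namely M1 (adjusted p = 0.0676), F1 (0.185), F2 (0.338), M2 (0.115), F3 (0.172) or F4 (0.118). It was also lost with no run term (0.876), only the 2 groups (0.152), no filter (0.0876) and quantile normalization again (0.0809). With mouse as a random block it had an unadjusted p = 0.0298 and did not pass. The call held with the stricter filter (0.0151), the mean of probe sets (0.0255), no intensity trend (0.0247) and the Eif2s3y covariate (0.0431). With the spread of all 14 arrays, tumours included, 0 genes passed within the female run. Only 84 had an unadjusted p under 0.05 there, where chance gives 382, so 0 calls say little. The difference for Irf7 was 3.43 within the female run (2 livers against 2) and 2.68 within the male run (1 against 1). It was 2.96 without the 6 libraries labelled female with Y-linked signal, where 0 genes passed in limma and 532 had an unadjusted p under 0.05.

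**Figure D3:**
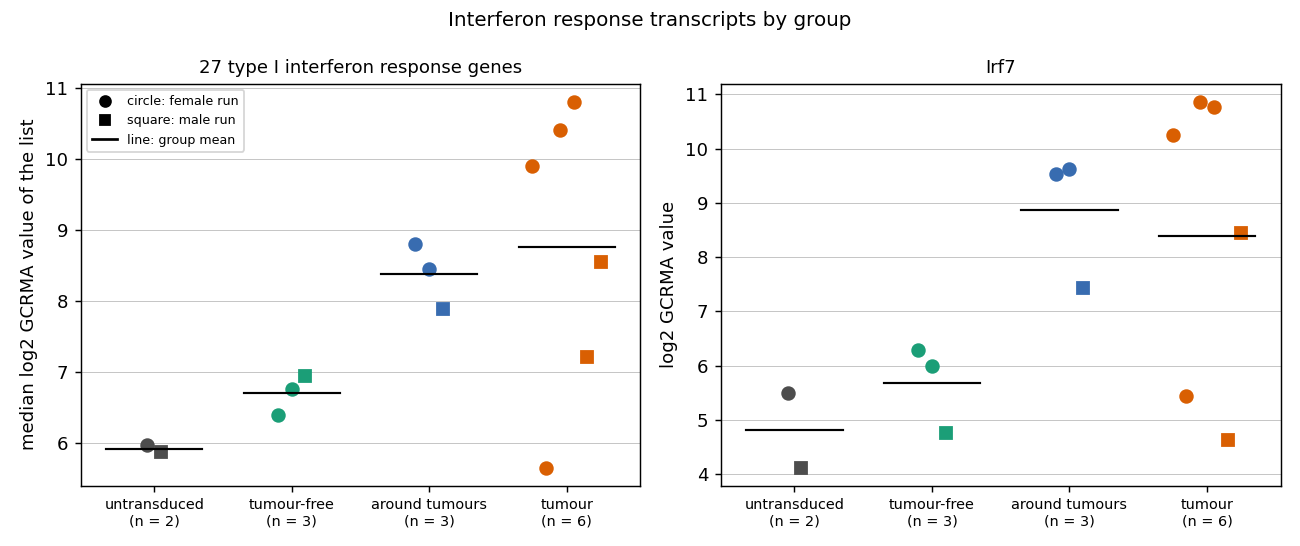
Median log2 GCRMA value of 27 type I interferon response genes (left y axis) and of Irf7 (right y axis) in each library, by group (x axis), with a line at the group mean and shape for the run. The list lies at 5.88 and 5.97 in untransduced, 6.40 to 6.95 in tumour-free and 7.89 to 8.81 in surrounding liver, and spreads from 5.66 (F1-T2) to 10.81 (F2-T2) in tumours.

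Tumour-free transduced against untransduced liver asks what transduction without a tumour leaves behind. Gdpd3, which encodes a phosphodiesterase of lysophospholipids, was 2.13 ± 0.0115 (SD, n = 3) in tumour-free transduced liver and 9.72 ± 0.863 (n = 2) in untransduced liver. It fell by 7.53 (SE 0.31, adjusted p = 6.1e-04 in limma) and was the only gene past the threshold, with 514 at an unadjusted p under 0.05. Over all libraries it was 10.33 in M-control, 9.11 in F-control, 8.39 in the library labelled F1-T2 and 2.08 to 2.14 in the other 11. These 11 values lie below the lower quartile of each array (2.40 to 2.54), near background, so the size of the differences given for this gene is not exact. The gene is on chromosome 7 and has Entrez identifier 68616. Without M-control 2 genes passed. The difference was -6.98 within the female run (2 livers against 1) and -8.19 within the male run (1 against 1). Fits of all 14 arrays take their spread from the tumours too. For this gene F1-T2 at 8.39 widens that spread, so such fits say little on this call. The call was lost with all 14 arrays and mouse as a random block (adjusted p = 0.524) and without the 6 libraries labelled female with Y-linked signal (0.135).

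Among the lists, interferon genes were higher in 22 of 27 cases, with a median of 0.26, Trim30a at 1.38 and Oas1a at 1.34. Female-biased liver genes were higher in 17 of 21, with a median of 1.91, Sult3a1 at 5.29 (-0.56 within the male run) and Cyp4a14 at 4.19, and male-biased ones lower in 16 of 17, with a median of -1.41, Hsd3b5 at -3.81 and Ugt2b38 at -3.30. Camera's adjusted p was 0.00035, 0.0097 and 0.028, and 0.692 for each with an estimated correlation. The other 9 lists past camera had adjusted p from 0.018 to 0.030, and also 0.692 with an estimated correlation. Matrix genes (median 0.27, Col5a2 1.83), stellate markers (0.53), P450 genes (0.08, Cyp2c37 5.12), p53 targets (0.38, the cell cycle inhibitor Cdkn1a 2.47), PPAR-alpha genes (0.14, Pdk4 3.03), mitosis (0.07) and cholesterol synthesis genes (0.20) were higher, and oxidative phosphorylation (-0.19) and ribosomal genes (-0.20) lower. Over all genes 0 members of the 12 lists passed, and adjusted over the list alone 1 p53 target and 1 PPAR-alpha gene did. Clock genes did not pass as a set (adjusted p = 0.32), with 5 of 17 past the threshold when adjusted over the list alone and 0 over all genes. The clock activator Arntl differed by 3.75 and the clock output gene Dbp by -4.74, and the hour of sampling is not given in the sources used here.

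The sex-biased lists follow the Xist signal, which only F3 carries among these 5 livers. The female-biased list level was 9.35 in F3, 5.50 and 5.18 in M2 and F4, and 4.23 and 3.71 in the 2 untransduced livers, both with Y-linked signal. Without F3 both lists had adjusted p = 0.4, and without the 6 libraries labelled female with Y-linked signal the medians were 0.22 and -0.345, so the difference cannot be ascribed to transduction.

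Each of those 12 list calls was lost when 1 liver was left out. Without F-control the adjusted p was 0.746 for female-biased, 0.622 for male-biased, 0.069 for stellate, 0.127 for matrix, 0.108 for p53 and 0.472 for mitosis genes. Without M-control it was 0.428 for oxidative phosphorylation, 0.0605 for ribosomal and 0.482 for cholesterol genes. Without M2 it was 0.0961 for interferon and 0.559 for PPAR-alpha genes, and without F4 it was 0.0542 for P450 genes. The medians of mitosis, cholesterol and PPAR-alpha genes were then at or just under 0 (-0.005, -0.00458 and -0.00143).

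Surrounding against untransduced liver joins both steps. Irf7 rose by 3.78 (SE 0.271, adjusted p = 0.0122 in limma) from 4.80 ± 0.969 (SD, n = 2), and Gdpd3 fell by 7.57 (SE 0.31, adjusted p = 5.9e-04). They were the only genes past the threshold among 555 at an unadjusted p under 0.05, and they share the surrounding or untransduced livers with the comparisons in which each was called before, so they are not independent calls. Both calls were lost with mouse as a random block and with only the 2 groups in the fit (adjusted p = 0.115 for Irf7 and 0.0702 for Gdpd3). Both held with no filter, quantile normalization again and no intensity trend. All 27 interferon genes were higher (median 1.41, adjusted p = 4.6e-31), 1 past the threshold over all genes and 22 when adjusted over the list alone. This list had adjusted p = 0.258 with an estimated correlation and passed in fry (0.042). Macrophage and Kupffer markers were higher in 18 of 19 cases (median 0.68, adjusted p = 6.2e-07), with Marco at 3.69, and matrix genes in 16 of 18 (median 0.57, adjusted p = 0.00019), with Col5a2 at 1.75 and Mmp12 at 1.58. Both had adjusted p = 0.448 with an estimated correlation and 0 members past the threshold over all genes, and 2 macrophage genes and 0 matrix genes passed when adjusted over the list alone. The neutrophil markers S100a8 and S100a9 differed by 2.48 and 2.32 without passing.

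Of the 16 lists past camera here, the other 13 were lost when 1 mouse was left out, and their adjusted p lay between 0.448 and 0.790 with an estimated correlation. Without F-control the call was lost for p53 targets (median 0.43, Cdkn1a 3.13), immediate early genes (0.46, Egr1 2.58), ER stress genes (-0.34, Asns -1.64), the proteasome (-0.16) and male-biased genes (-0.85), with adjusted p from 0.0725 to 0.554. The male-biased median turned to 0.15 without F-control and was -0.06 without F1. Without F1 it was lost for endothelial markers (0.24), PPAR-alpha genes (0.24) and female-biased genes (1.08), with adjusted p from 0.245 to 0.837, and F1 is the only one of these 5 livers with Xist signal. Without M-control it was lost for NRF2 targets (0.29) and oxidative phosphorylation genes (-0.11), at 0.114 and 0.565. Without F2 it was lost for P450 genes (0.24, Cyp2c37 4.79, Ces1g 1.92) and acute phase genes (-0.50), at 0.0592 and 0.302, and without M1 for pericentral genes (0.26), at 0.202. No member of these 13 lists passed over all genes, and 2 ER stress genes and 1 p53 target did when adjusted over the list alone. The call for Irf7 was lost without F1 (0.073), F2 (0.0972), M-control (0.133) or F-control (0.237). Within the female run (2 livers against 1) Irf7 differed by 4.09 and Gdpd3 by -7.01. Within the male run (1 against 1) they differed by 3.31 and -8.24.

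Tumours against the livers of tumour-free mice set tumour tissue beside transduced liver that stayed without tumours. All 32 mitosis genes were higher (median 2.57, Top2a 4.96, Ube2c 4.78), as were all 37 E2F targets (2.24, Mcm6 5.32, Lig1 4.08) and all 27 interferon genes (1.81, Oasl2 4.48, Oas1a 3.69). Ribosomal genes were higher in 25 of 26 cases (0.46, Rps25 1.93, Rps15 0.98). Camera's adjusted p for these 4 lists was 2.3e-14, 1.5e-13, 3.4e-09 and 5.0e-08, and 0.513 with an estimated correlation. Adjusted over the list alone 27, 30, 15 and 8 of their genes passed, against 0 over all genes. No gene passed in limma, with 1475 at an unadjusted p under 0.05 (934 higher and 541 lower) and a lowest adjusted p of 0.169. The 3 genes with the smallest p were Card10, a scaffold of NF-kappaB signalling, at 8.11 ± 0.683 (SD, n = 3 mice) against 5.70 ± 0.473 (n = 3), a difference of 2.40, the fetal liver protein gene Afp (3.92) and Cwf19l1 (-1.60). When each array was left out in turn, 198 genes passed without the library labelled F1-T2, 146 higher and 52 lower.

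Of the 19 lists past camera in that comparison, 13 were lower in tumours. Cholesterol (median -1.69), P450 (-0.71), bile acid (-0.76), PPAR-alpha (-0.51), stellate (-1.07) and hypoxia genes (-0.36) kept their call without any 1 mouse. Calls for 7 other lower lists were lost without 1 mouse, namely without F2 for pericentral (-1.70, adjusted p = 0.0792) and fatty acid synthesis genes (-0.61, 0.524), without M1 for periportal (-0.82, 0.11) and one-carbon genes (-0.28, 0.163), without F3 for acute phase (-0.67, 0.232) and secreted proteins (-0.13, 0.0725), and without F4 for male-biased genes (-0.93, 0.307). The male-biased median turned to 0.015 without F4 and 0.00925 without F2 (adjusted p = 0.154), and the call was lost without M1 (0.051) and M2 (0.217) too. The higher tumour markers (1.05, Vil1 5.03) were lost without F4 (0.155), and immediate early genes (0.83) without F2 (0.35). With an estimated correlation the adjusted p of these 15 lists lay between 0.513 and 0.645. Over all genes 0 of their members passed, and adjusted over the list alone 5 tumour markers, 4 bile acid genes and between 0 and 2 genes of each other list did. Clock genes did not pass as a set (adjusted p = 0.59), with 8 past the threshold adjusted over the list alone and 0 over all genes (Dbp 3.51, Per3 3.36).

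Tumours against untransduced liver gave a like picture of lists. All 32 mitosis genes (median 2.5, Cdc20 5.18, Mki67 5.16) and all 27 interferon genes (2.34, Oas1a 5.07, Oasl2 4.64) were higher, and all 17 male-biased genes were lower (-2.92, Elovl3 -4.90, Hsd3b5 -4.62). Their adjusted p was 3.3e-18, 9.0e-16 and 1.1e-05, and 0.626 with an estimated correlation, and adjusted over the list alone 21, 21 and 1 of their genes passed. E2F targets (1.93), ribosomal genes (0.35), tumour markers (1.80, Vil1 4.84, Prom1 4.69), p53 targets (0.57) and immediate early genes (1.01) were higher as well, and cholesterol (-1.16), bile acid (-0.81) and P450 genes (-0.46) lower, and these calls held without any 1 mouse. Calls for periportal (-1.01, adjusted p = 0.198) and oxidative phosphorylation genes (-0.15, 0.0997) were lost without M-control, and those for pericentral (-1.34, 0.946) and female-biased genes (0.91, 0.177) without F-control. These 12 lists had adjusted p from 0.626 to 0.682 with an estimated correlation, and 4 tumour markers, 2 p53 targets, 1 periportal gene and 0 others passed when adjusted over the list alone. In limma 0 genes passed over all genes, with 925 at an unadjusted p under 0.05 and a lowest adjusted p of 0.402, and 7 passed without the library labelled F1-T2. The 3 genes with the smallest p were Cdkn1a (3.31), Gdpd3 (-6.61) and Card10 (1.72).

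The female run against the male run in the 8 non-tumour livers separates labelled sex and array run together, which the design cannot part. Here 2197 genes passed in limma, 1179 higher and 1018 lower in the female run. The largest rises were Lcn2 (4.54), Prtn3 (4.29), Saa2 (4.26), Orm2 (3.94) and Tpgs1 (3.73), and the largest falls Resf1 (-4.29), Dbp (-4.15), the chromatin genes Atrx (-4.04) and Kdm5a (-3.88), and Arid5b (-3.86). Of 23 acute phase genes, 21 were higher (median 0.98), with Orm1 at 0.77, Itih4 at 0.64 and Serpina3n at 1.72, and 11 passed over all genes and 12 adjusted over the list alone. Of 18 cholesterol genes, 15 were higher (median 0.74), with Mvd at 3.42, Dhcr7 at 0.99 and Nsdhl at 0.71 and with Stard4 at -1.21 (Orm1 and Nsdhl turned to -0.38 and -0.45 with all 14 arrays and mouse as a random block), and 11 passed over all genes and 12 adjusted over the list alone. These 2 lists passed camera (adjusted p = 0.0014 each, and 0.956 with an estimated correlation). Endothelial and macrophage markers did not pass as sets (adjusted p = 0.053 and 0.077), with 5 and 4 genes past the threshold over all genes and 8 and 4 adjusted over the list alone, among them Eng (1.76), Oit3 (1.59), C1qc (2.22) and Cd68 (2.10).

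Male-biased liver genes differed by a median of -1.52 between the runs without passing (adjusted p = 0.056), with Hsd3b5 at -4.76 and Cyp4a12a at -3.95. Their list level was 12.20 in F2, 11.83 in F-control and 11.24 in F4, all labelled female with Y-linked signal, 8.71 in F1 and 6.43 in F3, and 12.35 to 12.60 in male livers. The count of genes was 469 without M2, 885 without F-control, 886 without M-control and 1194 without M1. It was 3 without the 6 libraries labelled female with Y-linked signal, which left 5 livers, and 2632 without the 2 livers with Xist signal, both fits chosen after seeing the data.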

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

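The tests of explanations, the fits without doubted libraries and the counts of other splits in this part were chosen only after the results were seen; the test of a tumour difference between mice and the gene count without F1-T2 were planned.

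Of the libraries labelled female, 6 carried Y-linked signal and no Xist, a signal outside the group comparisons. Male RNA mixed into female samples is excluded, since such a mixture would keep Xist, and the highest Xist value among the 6 was 2.05, and 2.60 on a second probe set. An exchange between the runs needs libraries labelled male without Y-linked signal, and there were 0. Sex or animal labels that do not hold remain open: male-biased liver genes lay at 11.24 or above in the non-tumour livers among the 6 and at 8.71 or below in the others labelled female, which is consistent with tissue of male animals. No biological explanation was tested, and which samples are concerned beyond these values cannot be said from the arrays.

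The library labelled F1-T2 stood apart from the other 5 tumours in 8 results, each as a difference from its own surrounding liver: Mki67 (-1.49), Fabp4 (-0.41), Rps25 (-1.02), Gdpd3 (6.29), Oas1a (-4.85), Arntl (-3.49), Cdkn1a (-4.12) and the ribosomal list (-0.175). Tissue of mouse F1 is excluded, since Eif2s3y was 6.03 higher than in the liver of F1. An exchange with a non-tumour library of this series was looked at through the mitosis list. It was at most 3.12 in any of them, against 4.28 in the lowest other tumour, so none of them carried the mitosis signal of the other 5 tumours. A tumour with little cell division would not be seen in this way, so an exchange is not excluded. A sample of another animal under this label remains open: the root mean square difference over genes was 0.323 to F-control, the smallest of 91 pairs, and 0.819 to the liver of F1. It may be liver of an animal close to F-control, and no biological explanation was tested.

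The female and male runs differed by 2197 genes in non-tumour liver, and none of 53 other ways to part the livers gave more than 2. So 1 of 54 splits was as large, the smallest share that 54 splits can give. In the other splits the difference between the runs adds to the spread, which can lower their counts. The splits therefore argue against chance but do not exclude it. Sex of the animals as the whole cause is excluded: among the 6 livers that all carried Y-linked signal, 2632 genes passed, and 1955 passed both with and without the 2 livers with Xist. A loss of 5' signal in the male run cannot be told apart from other differences between the runs, because the lowest beta-actin 3' minus 5' value of the male run lies 1.1 above the highest of the female run, with no overlap. The labelled sex stays open as a part of the difference. For lists all 54 splits gave at least the 2 lists of the real one, and the highest other gave 15, so the list count says nothing against chance.

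The other values that stood apart were these, each from 1 tumour against its own surrounding liver. C8a was at -10.74 in F2-T1. Psat1 was at 3.88, the one-carbon list at -0.66 and the periportal list at -3.10 in M1-T1. Kdm5a was at -2.92 and Eng at 0.93 in M1-T2. Of 100 genes and 32 lists looked at in the 6 tumours, 11 genes and 3 lists stood apart in this way. Chance gives about 1 in 20 for 6 independent values. Tumours of a mouse share the liver they are compared with, and the genes were those named in the text, so that rate cannot be applied here.

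In 4 results both tumours of M1 moved one way and all 4 libraries labelled as tumours of F1 and F2 the other: the PPAR-alpha list (a difference of 0.648), Dbp (-3.27), Arntl (1.68) and Cyp4a14 (3.84). They come from the same 100 genes and 32 lists, and among so many a few such patterns can arise by chance. These 4 differences take in the library labelled F1-T2, which did not match tissue of F1. For Arntl it lay at -3.49, apart from the other tumours, which enlarges the difference given. For the list the difference was not tested. For genes, the planned contrast of M1 with the mean of F1 and F2 called 0 genes in limma, with 143 at an unadjusted p under 0.05. It took its spread from the 2 tumours of each mouse, the library labelled F1-T2 among them, so 0 calls say little.

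Other splits of the same arrays were fitted for the remaining counts. A real count of 0 genes is reached by every split whatever the data, so it says nothing on chance. This holds for tumours against surrounding liver (81 splits with mouse as a block, the highest other 1750 genes, and 27 splits that take 1 array of each mouse as surrounding, the highest other 1) and against tumour-free liver (10 splits, the highest other 0). For lists in tumours against surrounding liver, 8 of 81 splits gave as many as the real 18, the highest other also 18, and 2 of the 27 did (highest other 18), so chance is not excluded.

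Without the library labelled F1-T2, 4 of 54 splits gave at least the real 12 genes, and the highest other gave 1205. All arrays of M1 stand on 1 side of that split, which leaves the tumour difference within F1 and F2, so the count of splits does not decide on chance. The split with 1750 genes is the same contrast with the library labelled F1-T2 placed among the surrounding livers. It sets F1-T1 and both F2 tumours apart from the other arrays of F1 and F2. That split was singled out for its high count and rests on these mice alone, so no conclusion is drawn from it. Without F1-T2, a split that sets the tumour M1-T2 with the surrounding livers of M1 and F2 gave 15 genes, as did its mirror. Both exceed the real 12 though they do not follow the tissue labels. With 1 array of each mouse as surrounding, the real split gave 12 genes and the highest other 5, and 1 of 18 is too few splits for a share under 0.05. The 10 splits of 6 mice are too few as well. For surrounding against tumour-free liver 3 gave at least the real 1 gene (highest other 3) and 7 at least the real 6 lists (highest other 14), and for tumours against tumour-free liver 1 gave the real 19 lists (highest other 18).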

How the results depend on the processing

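The list tests without the tumour labelled F1-T2 (also with an estimated correlation) and the fits without the 6 libraries labelled female with Y-linked signal, without the 2 livers with Xist and with the Eif2s3y covariate were chosen after seeing the data; all others were planned, for genes also the fits without F1-T2. Dim signal limits genes near the array background, and causes were not tested except where fewer arrays or more genes entered a fit. For tumour against surrounding liver (0 genes), 12 passed without F1-T2, 16 with the Eif2s3y covariate, and 0 to 12 when each replicate was left out. For surrounding against tumour-free liver (1 gene), 0 passed with no filter, quantile normalization, the female run only, mouse as a random block, within the female or the male run, only the 2 groups, no run term or without the 6 libraries, 3 with the covariate, and 0 to 1 without single replicates. For tumour-free against untransduced liver (1), 0 passed with the stricter filter, which dropped Gdpd3, the random block, within either run, only the 2 groups or without the 6 libraries, 2 with the female run only, and 1 to 2 without single replicates. For surrounding against untransduced liver (2), 0 passed with the random block, within either run, only the 2 groups or without the 6 libraries, 1 with no run term, and 1 to 3 without single replicates. Tumour against tumour-free liver (0) gave 6 with the random block, 198 without F1-T2 and 0 to 198 without single replicates; tumour against untransduced liver (0) gave 7 without F1-T2 and 0 to 7. The run count (2197) was 3844 with all probe sets, 985 with a 2-fold minimum, 3 without the 6 libraries and 469 to 2248 without single replicates. The test between mice (0) gave 4 with no filter.

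List counts fell to 0 with an estimated correlation in all 7 comparisons, and to 0 with fry in 6; fry gave 1 for surrounding against untransduced liver. Without F1-T2 the 3 counts with tumours were 0 as well with an estimated correlation. The run lists (2) were 5 with the mean of a gene's probe sets and 7 without the 6 libraries. Without single mice the list counts were 15 to 18 (tumour against surrounding), 5 to 11 (surrounding against tumour-free; 10 without M1, 11 without M2 or F3), 8 to 13 (tumour-free against untransduced), 8 to 17 (surrounding against untransduced; 8 without F1), 15 to 21 (tumour against tumour-free), 15 to 17 (tumour against untransduced) and 2 to 5 (runs).

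Some log2 values changed sign, none of a gene past the threshold except where said. For tumour against surrounding liver, Rbl2 was 0.10 with the mean of its probe sets, 0.09 within the male run and -0.14 to 0.035 without single replicates (0.03 without M1-T1, 0.035 without the surrounding liver of F2). E2f6 was 0.0875 with the female run only and within it, and -0.22 to 0.0875 without single replicates (0.0875 without the surrounding liver of M1, 0.08 without M1-T1, 0.025 without F2-T1). E2f5 was -0.10 without the 6 libraries and -0.045 (without the surrounding liver of F2) to 0.26 without single replicates. Within the male run Cyp1a2 was 0.035, E2f8 -0.015, Glul 0.545, Gulo 0.66 and Rb1 -0.33, Saa2 was 0.51 for surrounding against tumour-free liver and Sult3a1 -0.56 for tumour-free against untransduced liver (-0.22 without the 6 libraries). In the run comparison Nsdhl and Orm1, past the threshold there, were -0.45 and -0.38 with the random block, and the cause was not tested. Camera's direction changed for female-biased genes in surrounding against untransduced liver (median 0.085 without the 6 libraries, and -0.08 without F1 to 1.99 without F2, with 0.10 without F-control), for male-biased genes in tumour against surrounding liver (-2.50 without F1 to 0.26 without F2) and for pericentral genes in tumour against untransduced liver (0.22 without the 6 libraries). The male-biased median changed sign, though camera's direction did not, for surrounding against untransduced liver (0.15 without F-control, 0.04 without the 6 libraries) and tumour against tumour-free liver (0.015 without F4, 0.00925 without F2). For tumour-free against untransduced liver the mitosis, cholesterol and PPAR-alpha medians fell to between -0.00667 and -0.00125 under some of these settings. Of the values of 134 differences of named genes (a gene in 2 comparisons counts in both) under all alternatives, 2508 kept direction and side of the threshold, 111 lost the call, 49 gained it and 21 changed sign. For 88 list calls, summed over the 7 comparisons, 544 kept both, 342 lost the call and 5 changed direction.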

Other observations

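The test of a hypothesis in this part was chosen only after the results were seen, as were the genes named here beyond the rule.

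The tumour M1-T1 carried transcripts of the fetal liver and of beta-catenin targets. Afp was 14.15 and Gpc3 9.69, against 4.09 and 2.01 in its own surrounding liver. The glutamine synthetase gene Glul was 14.69 (13.33 in surrounding liver), the ammonium transporter gene Rhbg 10.08 (4.69), and the Wnt feedback genes Axin2, Lgr5, Nkd1, Sp5 and Notum were 8.38 (5.41), 9.70 (7.01), 6.91 (2.97), 7.66 (3.18) and 8.87 (6.43). Periportal enzymes were low: Hal was 6.91 against 11.44 and Cps1 11.13 against 14.23. The macrophage list stood at 5.31 in this tumour and between 7.88 and 9.84 in the other 13 libraries. The median of 18 pericentral and beta-catenin genes was 1.65 above its own surrounding liver, at percentile 100 of 10000 random lists, and the periportal list was at percentile 0. No explanation of these values was tested.

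The other tumours carried other transcripts. The growth factor gene Igf2 was 12.11 in F1-T1 and at most 2.44 in the other 13 libraries. In both tumours of F2 the neutrophil granule genes Camp (7.82 and 9.88, against 5.46 in the surrounding liver of F2), Ngp (8.62 and 11.05, against 6.09) and S100a8 (10.98 and 12.51, against 8.25) were high. The neutrophil list (8 genes) differed by 2.69 and 5.13 and the T and NK cell list (3 genes) by 2.13 and 1.17 in F2-T1 and F2-T2. In F2-T1, 1 of the 3 T and NK cell genes was at least 2-fold lower.

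Interferon genes were high in the livers of the tumour-bearing mice, where macrophage markers were high too. More macrophages as the whole cause stay open, because 2 measures part. The mean level of macrophage and Kupffer markers differed by 0.237 between surrounding and tumour-free livers (SD within groups 0.563, n = 3 each), against 1.68 for the interferon list. The fitted medians were 0.60 and 1.15, a gap of 0.55 that lies under 2 SD (1.13). A response to the tumours, to the vector or to age may underlie the difference, and none of these was tested.

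The clock genes of the library labelled F1-T2 lay close to those of F-control, with a root mean square difference of 0.276 over 17 genes, and 2.31 from the liver of its own mouse. The other 5 tumours lay 0.250 to 1.54 from their own surrounding liver.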
